A study of Drosophila melanogaster with 35 samples.

How the data were processed

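Total RNA from dissected Drosophila melanogaster wings was labelled with Cy3 and hybridised to 1-colour NimbleGen expression arrays by a microarray facility, with 10 wings per sample. Animals carried the apterous-Gal4 driver with UAS-GFP and a temperature-sensitive Gal80 repressor under the tubulin promoter, were grown at 18 °C and were moved to 28 °C to allow transgene expression. The control strain carried no further transgene, the line called E2F1DP carried UAS transgenes for E2F1 and DP, and the line called Cbt carried one for Cabut. Samples were grouped by line and stage as the labels give them, into 9 groups: wandering larvae of the last instar (L3), 24h and 36h after pupa formation. Each group had 4 arrays except E2F1DP at L3, which had 3, because 1 sample did not pass the submitters' quality control.

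The authors deposited 1 file per array with an expression value per FlyBase transcript ID, on a linear intensity scale, made by RMA per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays it is run on and summarises the probes of a transcript. Which arrays were run together, the RMA settings, its version and the annotation release were not stated. The deposited series table holds the same values as log2 numbers, and the largest difference from log2 of the per-array values was 5.00001e-09. Intensities ran from 14.6 to 64595 over the 35 arrays. The arrays hold 15473 transcripts, 10111 of them with 5 probes, 5359 with 4 and 3 with 3. The median log2 intensity of an array lay between 9.25 and 10.02. No background level or detection call was used, and the number of arrays limits the precision. The highest correlation between any pair of arrays was 0.996, with a root mean square difference of at least 0.31 on the log2 scale for every pair, so no array was a copy of another.

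Values were taken as log2 of the deposited intensity and analysed in R 4.3.3 with limma 3.58.1. One linear model with 9 group means was fitted to all 35 arrays and moderated by empirical Bayes, with 26 residual and 2.86 prior degrees of freedom. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 15473 transcripts of a contrast. The 16 contrasts were each transgene line against control at each stage, Cbt against E2F1DP at each stage, the 3 pairs of stages in control, and, for each line, the change of its effect from L3 to 24h and from 24h to 36h. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reference tables and figures. These contrasts, the threshold, the gene lists, the rule for named genes and all alternatives other than those said to have been added were chosen before the data were examined.

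The files identify features by FlyBase transcript ID only. IDs were looked up among the synonyms of the NCBI RefSeq gene table for Release 6 of the genome. Of the 15473 IDs, 44 appeared there, 17 under 1 gene and 27 under several genes, and 15429 were not matched. For some of the 17, the synonym marks the main open reading frame of the transcript, so the probes report on a transcript that may carry another frame. No coordinates are given, because the build behind the array design was not stated. None of the 478 entries of the 27 gene lists fixed in advance, which covered cell cycle, growth, metabolism, signalling, stress and cell type markers, matched an ID, so the planned list tests and the planned look at cell type markers were not run. The levels of E2F1, DP and Cabut themselves were not analysed here. The rule for named genes took E2F1, DP and Cabut, the 10 transcripts with the largest rise and the 10 with the largest fall among calls without overlap between the groups for each line against control, 5 each way for other contrasts, and called members of the lists. Since nearly all of these have no name, 2 IDs that rose and 2 that fell are given as examples. After the data were seen, all 17 transcripts with 1 gene were added as named genes, whatever their values.

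Also added after the data were seen were groups of transcripts that rose or fell in control development, each defined on control arrays that the tested contrast did not use. Their members were counted among the calls and tested against all other transcripts with camera in limma, at its preset correlation and at an estimated one, with Benjamini-Hochberg adjustment over 12 sets. The place of an array in development was measured by projecting it on the line from the control mean of one stage to that of another, so that the first mean lies at 0 and the second at 1. Arrays at 24h were placed on the line from L3 to 36h, and arrays at 36h on the line from L3 to 24h. Groups were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 6 tests.

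E2F1DP and Cbt were compared with the same control arrays. Their overlap was set beside the product of the list sizes over all transcripts, taken per direction, and beside the 6 ways to give 2 control arrays to one line and 2 to the other. The correlation and covariance of their changes were set beside 100 simulations of unchanged groups against shared simulated controls. In the simulations all arrays, controls included, were noise drawn from the fitted spread of each transcript. The noise was independent between transcripts, so deviations that many transcripts of a real array share are not part of the simulated values.

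The arrays came on 9 slides of up to 4. Slide numbers used here are arbitrary. Lines and stages were spread over the slides unevenly, and no slide held both a Cbt and a control array at 24h or at 36h. Where a slide held both groups of a contrast, transcripts were called in a model without any array of that slide, and the sign of their change was then read on the slide, a check added after the data were seen. Whether replicate numbers pair the samples was checked by correlating deviations from the group mean between samples that share a number. In 46 pairs over 12 contrasts, every pair of a contrast passed 0.1 only for E2F1DP against control at 24h, where r lay between 0.31 and 0.73 over 4 pairs. At 24h, 3 of 4 pairs passed 0.1 for Cbt against control (r from 0.02 to 0.41) and for Cbt against E2F1DP (0.04 to 0.43). Pairing of the Cbt samples of 24h is thus not excluded. By this check the numbers may pair the samples of E2F1DP and control at 24h, which comes from the data alone, since the labels call the samples independent replicates. Replicate 3 stood apart in the same way in both of these groups. Deviations sum to 0 within a group, so this alone pushes the other pairs to agree, and the 4 pairs are not separate evidence. The model has no pairing, and the replicate number as a term is among the alternatives. An exact test of positions over pairs and camera with the replicate number in the design were added after the data were seen.

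The alternatives were the slide as a fixed or a random term, the replicate number or the array position as a term, the series table, median centring, quantile normalization, leaving out the dimmest 25% of transcripts, an intensity trend in the variance model, only the compared groups in the model, array weights, a log2 change of at least 1, an adjusted p under 0.01, each array left out in turn, control arrays split between the lines, and only transcripts changed between control stages. Keeping each feature apart changes nothing here, since none was merged. Added later were leaving out control replicate 3 and E2F1DP replicate 3 at 24h together, and a direct comparison of each line at 36h with control at 24h.

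The calls were tested on simulated data with the real means and spreads of 15473 transcripts, 200 of them changed, in 20 runs. For E2F1DP against control at 24h, 10.1% of changes of 0.5 on the log2 scale, 56.2% of changes of 1 and 91.8% of changes of 2 were recovered, and 5.66% of calls were false. At L3, with 3 arrays against 4, the shares were 7.39%, 50.7% and 89.5%, with 5.08% of calls false. The simulated noise was independent between transcripts and had 1 spread per transcript for all groups. Real arrays varied around their group means with an SD from 0.184 to 0.682. The shares at 24h and L3 thus reflect the number of arrays and may not hold for the real data. Simulated positions on the developmental line came back within 0.00673.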

Results

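The study measured transcript levels on 35 arrays of dissected wings from 3 fly lines at 3 stages, L3, 24h and 36h after pupa formation. Its series title asks how overexpression of E2F1 with DP, a transcription factor pair that drives genes of DNA replication, compares with that of Cabut, a zinc finger transcription factor. The transgenes were driven by apterous-Gal4, which is active in the dorsal cells of the wing. Each group had 4 samples, and E2F1DP at L3 had 3. The values are the log2 of RMA intensities, and the array medians lay between 9.25 and 10.02. Of the 15473 transcripts, 17 could be tied to 1 gene and are named here. Errors of log2 changes are standard errors (SE) of limma and errors of levels are standard deviations (SD).

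The comparison of stages in control wings sets the background against which the transgenes act. NaPi-III, by its name a type III sodium-phosphate cotransporter, went from a log2 level of 12.11 ± 0.11 (SD, n = 4) at L3 to 8.12 ± 1.18 (SD, n = 4) at 24h, a change of -3.99 (SE 0.40, limma adjusted p = 1.59e-09). LanA, the alpha chain of laminin in basement membranes, changed by -2.34 (SE 0.21, adjusted p = 1.53e-10), and sle, a nucleolar protein, by -1.75 (SE 0.20, adjusted p = 1.71e-08). Fatp1, a fatty acid transport protein, rose late, by 2.50 (SE 0.17, adjusted p = 3.93e-12) from 24h to 36h, when its level went from 11.27 ± 0.34 to 13.78 ± 0.19 (SD, n = 4). Of the 17 named genes, 9 fell and 1 rose from L3 to 24h, and 2 fell and 5 rose from 24h to 36h. With the slide as a term the falls of fend (adjusted p = 0.0902), rdx (0.368), SuUR (0.0986) and Uba1 (0.0729) to 24h ended, and so did the later calls of HDAC3 (0.377), SuUR (0.148), rdx (0.32) and CG16974 (0.0663). Each of these changes kept its direction. The median SE over all transcripts was wider with the slide, at 0.308 for the earlier and 0.315 for the later comparison against 0.235. The rise of alpha-Spec and the fall of Dyrk3 after 24h ended when only the compared groups were modelled (0.071 and 0.114), so of the later calls that of Fatp1 alone held under every scaling and model tried. Across all transcripts, 2712 rose and 2942 fell from L3 to 24h, 1629 rose and 1958 fell from 24h to 36h, and 3320 rose and 3732 fell from L3 to 36h. Between 24h and 36h 1999 transcripts passed with the slide as a term in the model, against 3587 without it. Control arrays of L3 and 36h met on slides 2 and 3, where 96.5% and 99.1% of the transcripts called between these stages without the arrays of that slide had the same sign of change.

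The comparison of E2F1DP with control at 24h asks what E2F1 and DP do to expression in the pupal wing. NaPi-III stood at 12.68 ± 0.21 in E2F1DP wings and 8.12 ± 1.18 in controls (SD, n = 4 each), higher by 4.57 (SE 0.40, limma adjusted p = 2.29e-10). SuUR, which suppresses the replication of late-replicating heterochromatin in polytene chromosomes, was higher by 1.97 (SE 0.25, adjusted p = 3.8e-07). HDAC3, a histone deacetylase, was higher by 0.79 (SE 0.11, adjusted p = 1.6e-06) and sle by 1.34 (SE 0.20, adjusted p = 3.29e-06). Wdr24, a subunit of the GATOR2 complex of nutrient signalling, was higher by 0.82 (adjusted p = 0.000677), and Uba1, the enzyme that activates ubiquitin, by 0.67 (adjusted p = 0.0018). LanA was lower, by -0.96 (SE 0.21, adjusted p = 0.000632), and CG16974 by -0.39 (adjusted p = 0.0469). The 6 named genes that were higher had all fallen from L3 to 24h in control wings, a comparison that uses the same control arrays. Of the 9 that fell there, LanA was lower still in E2F1DP wings, and fend and rdx did not pass (adjusted p = 0.191 and 0.701). Among the unnamed transcripts, FBtr0074485 stood at 12.37 ± 0.49 in E2F1DP wings and at 6.06 ± 0.30 (SD) in controls, where it had been at 11.33 at L3. A mean under 6.20 is that of the dimmest 25% of transcripts and was not shown to lie above background, so the difference of 6.31 (SE 0.34) has no exact size. The call of CG16974 ended with the slide as a term (adjusted p = 0.208), with median centring (0.169) and without any of control replicates 1, 2 and 4 and E2F1DP replicates 1, 2 and 3 (0.0579 to 0.159). The calls of Wdr24 and Uba1 ended when only the compared groups were modelled (adjusted p = 0.0691 and 0.0674).

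At 24h the transcripts changed by E2F1DP were mainly those of control development, in the opposite direction. Of the 3732 transcripts that fell from L3 to 36h in control, measured on arrays that this contrast does not use, 1328 were higher in E2F1DP and 183 were lower, where independent lists would share 462 and 544. Of the 3320 that rose in control, 1433 were lower and 106 were higher, against 484 and 411. The camera test of limma gave adjusted p = 3.32e-25 for the group that fell and 1.11e-24 for the group that rose, and both calls held with an estimated correlation (0.00194 and 0.0115). In total 1917 transcripts were higher and 2254 lower, which is 27.0% of those measured, and 2000 of them changed at least 2-fold. Median centring moved the share of higher calls from 46.0% to 58.0%. The count was 3442 in the model with the slide, 2186 when only the compared groups were modelled and 5308 with array weights. Slides 5 and 6 held both groups, and of the transcripts called without the arrays of that slide, 83.4% and 73.6% had the same sign on it. Slide 5 held control replicate 3, and slide 6 held E2F1DP replicate 3 as its only E2F1DP array. Both of these arrays stood apart from their groups.

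**Figure D1:**
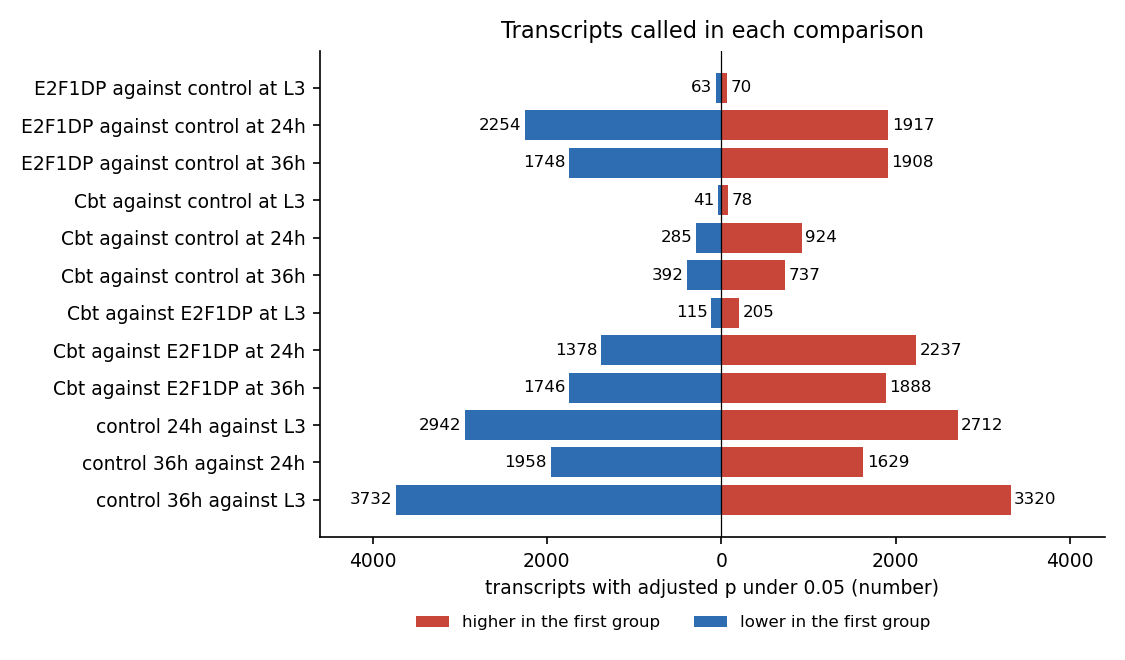
Number of transcripts called higher (right) or lower (left) in the first group of each comparison between lines and between control stages (bars, limma, Benjamini-Hochberg adjusted p under 0.05). E2F1DP changed 133, 4171 and 3656 transcripts at L3, 24h and 36h, and Cbt changed 119, 1209 and 1129.

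At 36h the comparison asks whether these changes last. NaPi-III was still 4.0 (SE 0.40, limma adjusted p = 2.57e-09) higher in E2F1DP wings than in control, SuUR was 1.52 (SE 0.25, adjusted p = 2.19e-05), HDAC3 0.94 (SE 0.11, adjusted p = 6.27e-08) and sle 0.78 (SE 0.20, adjusted p = 0.00297) higher. Fatp1 was lower by -2.31 (SE 0.17, adjusted p = 4.37e-12), at 11.47 ± 0.17 against 13.78 ± 0.19 (SD, n = 4), so that its control rise after 24h was nearly missing in E2F1DP wings. The difference for fend was -1.87 (SE 0.24, adjusted p = 3.22e-07), and that for CG16974 was -0.54 (adjusted p = 0.00514). The effects on Fatp1 and fend at 36h were more negative than those at 24h, by -2.26 (SE 0.24, adjusted p = 7.04e-08) and -1.43 (SE 0.34, adjusted p = 0.00482). Wdr24 and Uba1, at 0.26 and 0.32 higher, did not pass (adjusted p = 0.355 and 0.178), and the change from their 24h effects did not pass either (0.207 and 0.434). FBtr0074485 stood at 13.56 in E2F1DP wings and 5.52 in controls, and FBtr0100257 at 5.41 ± 0.24 in E2F1DP wings and 14.98 ± 0.29 (SD) in controls, where it had been at 5.60 at 24h. Each lower level is again among the dimmest, so the sizes of these differences are not exact. With the slide as a term the call of sle at 36h ended (0.66, adjusted p = 0.0603), and so did the change of the effect on fend (-1.30, adjusted p = 0.0655), which also ended when only the compared groups were modelled (0.0547).

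**Figure D2:**
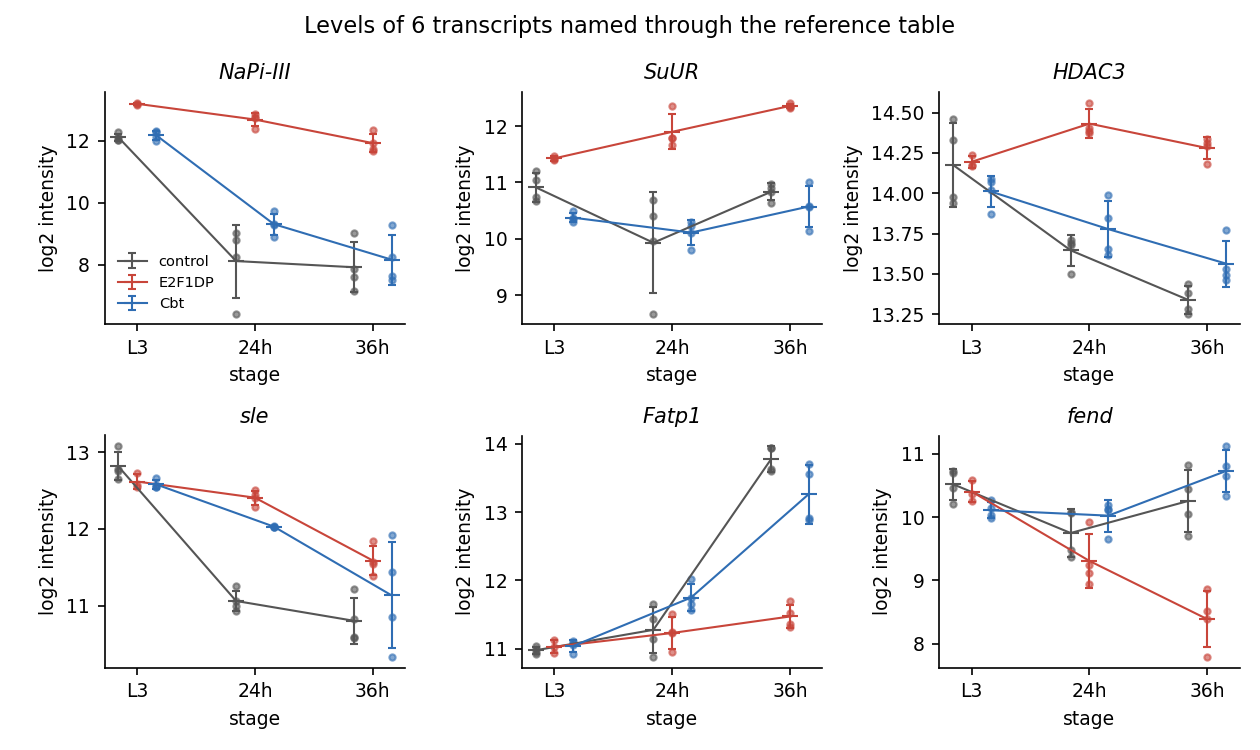
Log2 RMA intensity of 6 named genes in control, E2F1DP and Cbt wings at L3, 24h and 36h, with 1 point per array, lines through the group means and bars of 1 SD; the axes do not start at 0. NaPi-III falls to 8.12 at 24h in control and stays at 12.68 in E2F1DP, and Fatp1 reaches 13.78 at 36h in control and 11.47 in E2F1DP.

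Across all transcripts 1908 were higher and 1748 lower in E2F1DP at 36h, 1821 of them at least 2-fold, and median centring moved the share of higher calls from 52.2% to 48.3%. Of the 2942 transcripts that fell from L3 to 24h in control, 1103 were higher and 192 lower in E2F1DP, where independent lists would share 363 and 332. Of the 2712 that rose, 755 were lower and 178 higher, against 306 and 334. The camera test gave adjusted p = 2.33e-20 and 1.06e-08. With an estimated correlation the call held for the transcripts that fell (0.0192) and ended for those that rose (0.0586). The contrasts at 24h and 36h share no array, and 1144 transcripts were higher and 835 lower in both, where independent lists would share 236 and 255, while 154 changed in opposite directions. At 36h 2697 transcripts passed in the model with the slide and 5202 with array weights. Slide 2 held both groups, and 97.1% of the transcripts called without its arrays had the same sign on it.

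**Figure D3:**
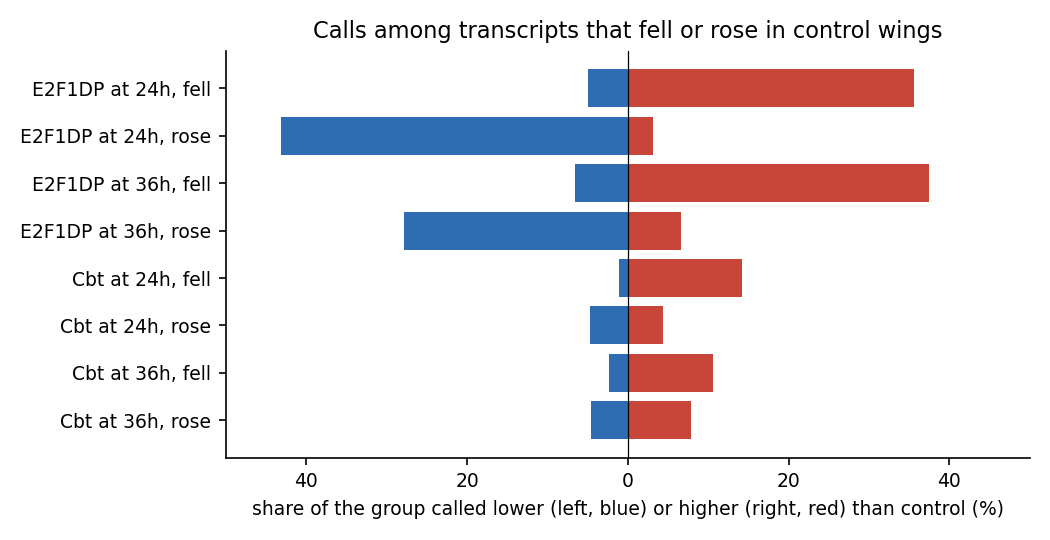
Percent of the transcripts that fell or rose in control development called higher (right) or lower (left) in each line than in control at 24h and 36h (bars), with groups defined on control arrays not used in the contrast. Of transcripts that fell in control, 35.6% were higher in E2F1DP at 24h and 14.2% in Cbt.

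In larval wings E2F1DP changed far fewer transcripts, 70 higher and 63 lower, in a model with 1 spread per transcript for all groups. The E2F1DP arrays varied around their group mean less at L3 (SD 0.184 to 0.203) than at 24h (0.325 to 0.682). The counts of the stages thus do not measure how far the effect differs in size between them. Median centring moved the share of higher calls from 52.6% to 65.9%, and without control replicate 4 the counts were 37 and 51, so the direction of any excess is not settled. None of the 17 named genes passed (limma, adjusted over all transcripts), and 2 of them had an unadjusted p under 0.05. NaPi-III stood at 13.19 ± 0.04 (SD, n = 3) against 12.11 ± 0.11 (SD, n = 4), a difference of 1.08 (SE 0.43, adjusted p = 0.388), and LanA differed by -0.79 (SE 0.22, adjusted p = 0.112). The effect at 24h exceeded that at L3 for NaPi-III by 3.49 (SE 0.59, adjusted p = 8.54e-05), for sle by 1.54 (SE 0.29, adjusted p = 0.000359), for HDAC3 by 0.77 (SE 0.16, adjusted p = 0.00137) and for SuUR by 1.46 (SE 0.37, adjusted p = 0.0084, or 0.106 when only the compared groups were modelled). Of the 133 changed transcripts, 98 were changed in the same direction at 24h, and 46 were higher and 27 lower at all 3 stages. The count was 79 with the slide as a term, 51, 64 and 53 without E2F1DP replicate 1, 2 or 3, and 88 without control replicate 4, but 206 without control replicate 3 and E2F1DP replicate 3 of 24h and 801 with array weights. Slides 3 and 4 held both groups, and of the transcripts called without the arrays of that slide, 100% of 55 and 98.2% of 57 had the same sign on it.

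The comparison of Cbt with control asks the same of Cabut, and few named genes answered it. At 24h sle was higher by 0.97 (SE 0.20, limma adjusted p = 0.00114), at 12.03 ± 0.0093 against 11.06 ± 0.14 (SD, n = 4), and no other named gene passed. NaPi-III was higher by 1.19 (SE 0.40, adjusted p = 0.0651) and did not pass. At L3 and 36h none of the 17 named genes passed (limma), with 3 at an unadjusted p under 0.05 at each of these stages. At 36h Fatp1 stood at 13.27 ± 0.43 against 13.78 ± 0.19 (SD, n = 4), a difference of -0.51 (SE 0.17, adjusted p = 0.0636). Some unnamed transcripts differed at every stage. FBtr0077115 was higher in Cbt wings by 5.75, 5.39 and 6.34 at L3, 24h and 36h, each with SE 0.38, and FBtr0088213 was lower by -3.27, -5.62 and -5.93, each with SE 0.24, where its Cbt levels of 5.70 and 5.67 at 24h and 36h are among the dimmest and leave the sizes inexact. With the slide as a term the call of sle ended (0.81, adjusted p = 0.152). No slide held both groups at 24h, and the median SE over all transcripts was 0.316 in that model against 0.235.

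Cbt raised more transcripts than it lowered as the values were deposited: 78 higher and 41 lower at L3, 924 and 285 at 24h, and 737 and 392 at 36h. Median centring shifted the median change of all transcripts at 24h from -0.01 to -0.20 and the share of higher calls from 76.4% to 53%, so the excess of higher calls at 24h depends on the scaling. Of the 3732 transcripts that fell from L3 to 36h in control, 530 were higher and 39 lower in Cbt at 24h, where independent lists would share 223 and 68.7 (camera adjusted p = 1.94e-08, or 0.0586 with an estimated correlation, which ended the call). With the replicate number in the design, camera with an estimated correlation gave adjusted p = 0.0455 for this group, so the call depends on the model. Of the 3320 that rose, 156 were lower and 147 higher, against 61.2 and 198 (camera adjusted p = 0.0262, or 0.666). At 36h, of the 2942 that fell from L3 to 24h in control, 312 were higher and 69 lower, against 140 and 74.5 (camera adjusted p = 2.14e-06, or 0.244), and of the 2712 that rose, 213 were higher and 125 lower (camera adjusted p = 0.714). Between 24h and 36h, 373 transcripts were higher at both stages and 65 lower at both, where independent lists would share 44.0 and 7.22, and 33 changed in opposite directions. At L3, 24h and 36h 51, 392 and 622 transcripts passed in the model with the slide, while array weights gave 458 at L3 and 1823 at 36h, and modelling only the compared groups gave 443 at 24h and 698 at 36h. Since no slide held both groups at 24h or 36h, a comparison within slides could be made at L3 alone, where 92.2% of the 64 transcripts called without the arrays of slide 1 had the same sign on it.

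The direct comparison of Cbt with E2F1DP asks where the effects of the transgenes part. At 24h NaPi-III was lower in Cbt than in E2F1DP wings by -3.37 (SE 0.40, limma adjusted p = 1.38e-07), SuUR by -1.79 (SE 0.25, adjusted p = 2.86e-06) and HDAC3 by -0.65 (SE 0.11, adjusted p = 3.64e-05), while LanA was higher by 1.00 (SE 0.21, adjusted p = 0.000508). At 36h NaPi-III differed by -3.76 (adjusted p = 1.31e-08), SuUR by -1.79 (adjusted p = 2.53e-06) and HDAC3 by -0.72 (adjusted p = 8.76e-06), and fend and Fatp1 were higher in Cbt by 2.34 (adjusted p = 6.83e-09) and 1.80 (adjusted p = 1.45e-09). Of the 17 named genes, 4 were higher and 3 lower in Cbt at 24h, and 3 were higher and 4 lower at 36h. At 24h the higher calls of fend, Fatp1 and CG16974 ended with the slide as a term (adjusted p = 0.0527, 0.145 and 0.0654), with median centring (0.232, 0.366 and 0.266) and when only the compared groups were modelled (0.0941, 0.0999 and 0.0981). Their changes were 0.716, 0.519 and 0.523 in the main model and 0.758, 0.499 and 0.482 with the slide. Median centring lowered them to 0.416, 0.218 and 0.223. At 36h the higher call of CG16974 and the lower one of His4r ended with the slide as a term (0.0623 and 0.054) and when only the compared groups were modelled (0.125 and 0.0999). At L3 SuUR alone passed, at -1.05 (SE 0.27, adjusted p = 0.035), a call that ended without any 1 of the 7 arrays (0.06 to 0.153) and with the slide as a term (0.431). Across all transcripts 205 were higher and 115 lower at L3, 2237 and 1378 at 24h, and 1888 and 1746 at 36h. At 24h median centring shifted the median change of all transcripts from 0.04 to -0.26 and the share of higher calls from 61.9% to 29.4%, and at L3 it moved that share from 64.1% to 47.8%, so the direction of the excess is not settled at either stage. In the model with the slide 98, 2553 and 2864 transcripts passed at the successive stages, and at L3 2089 did with array weights, while at 24h 1968 did when only the compared groups were modelled. Without E2F1DP replicate 1, 2 or 3 the count at L3 was 173, 212 and 182. Slides 9 and 7 held both groups at 24h and 36h, and 94.4% and 98.0% of the transcripts called without the arrays of that slide had the same sign on it.

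Both lines often changed the same transcripts the same way. At 24h 500 transcripts were higher and 198 lower in both lines, and 72 changed in opposite directions, where independent lists would share 114 and 41.5. At 36h 386 were higher, 265 lower and 68 opposite, against 90.9 and 44.3. At L3 14 were shared, 3 higher and 11 lower, and 3 were opposite, against 0.353 and 0.167. That count of 14 was 7, 9 and 7 without E2F1DP replicates 1, 2 and 3, and 9 and 8 without Cbt replicates 2 and 3. Among the named genes sle was higher in both lines at 24h. Both lines share their control arrays. When these were split between the lines, they shared 328 to 530 transcripts at 24h, 314 to 425 at 36h and 3 to 5 at L3. Across transcripts, which are not independent replicates, the log2 changes of both lines had r = 0.53 and rho = 0.50 at 24h and r = 0.48 and rho = 0.39 at 36h, where simulated unchanged groups had r = 0.50 at both stages. The covariance of the changes was 0.274 at 24h and 0.218 at 36h, above the simulated 0.0461 and 0.0463, and at L3 it was 0.0419 against 0.0464. With the slide as a term the shared counts were 4, 227 and 362 at L3, 24h and 36h, and with array weights they were 83 at L3 and 1040 at 36h.

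The last comparison asks where the wings of each line lay on the path of control development. On the line from control L3 at 0 to control 36h at 1, control wings at 24h lay at 0.689 ± 0.0219, Cbt wings at 0.569 ± 0.0477 and E2F1DP wings at 0.331 ± 0.0346 (SD, n = 4 each). E2F1DP lay -0.358 and Cbt -0.120 from control, and Cbt lay 0.238 above E2F1DP, each with a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give (Benjamini-Hochberg adjusted 0.0343 over 6 tests). The replicate numbers of E2F1DP and control at 24h passed the check for pairing, and over these 4 pairs the exact p of the -0.358 is 0.125, the smallest possible, so this call ends if the samples are paired. The differences within pairs ran from -0.389 to -0.319. Positions of Cbt at 24h were not tested over pairs. With 4 pairs no exact p can lie under 0.125, so the Cbt calls at 24h rest on independent samples. At 36h, on the line from control L3 to control 24h, control wings lay at 1.03 ± 0.0301, E2F1DP wings at 0.791 ± 0.0437 and Cbt wings at 0.963 ± 0.0434 (SD, n = 4 each). E2F1DP lay -0.235 from control (exact permutation p = 0.0286, adjusted 0.0343) and Cbt 0.171 above E2F1DP (exact p = 0.0286, adjusted 0.0343), while Cbt and control were not told apart (-0.0637, exact p = 0.0857), except without control replicate 1 of 24h (-0.0684, exact p = 0.0286). Within slides the difference between E2F1DP and control was -0.316 and -0.373 on slides 5 and 6 at 24h, and Cbt lay above E2F1DP by 0.206 on slide 9 at 24h and by 0.225 on slide 7 at 36h, each on the line from L3 to 36h. Across transcripts, the correlation of the E2F1DP effect with control development on other arrays was r = -0.60 and rho = -0.50 at 24h, r = -0.32 and rho = -0.30 at 36h, and r = -0.04 and rho = 0.02 at L3. For Cbt it was r = -0.29 and rho = -0.19 at 24h, r = -0.14 and rho = -0.15 at 36h, and r = -0.15 and rho = -0.19 at L3. Leaving out 1 array moved r at L3 between -0.113 and 0.0505 for E2F1DP, so its sign is not settled, and between -0.214 and -0.0504 for Cbt. The slide as a term moved r for Cbt at 36h to -0.0684.

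**Figure D4:**
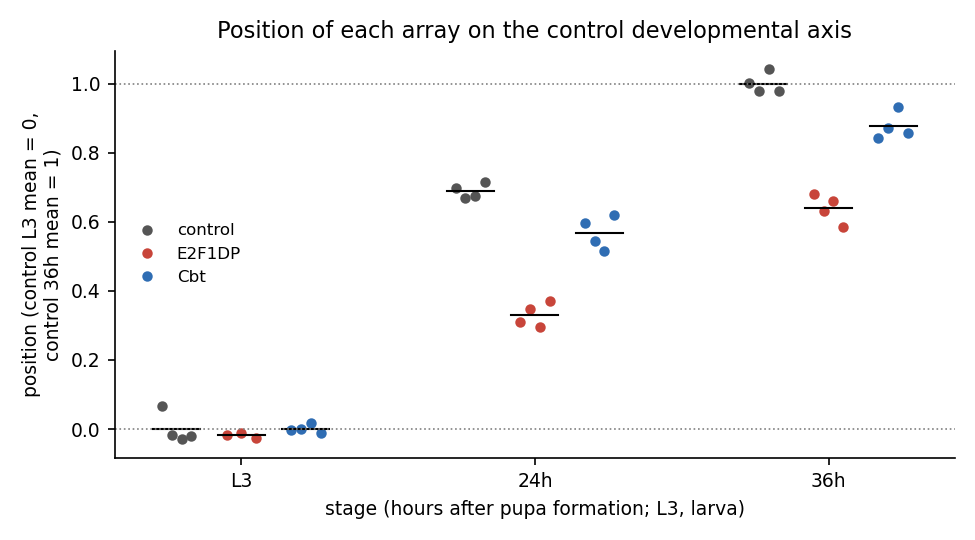
Position of each array on the line from control L3 (0) to control 36h (1), by line and stage, with 1 point per array and bars for the group means. At 24h the means are 0.689 for control, 0.569 for Cbt and 0.331 for E2F1DP, and at 36h the means of Cbt and E2F1DP are 0.876 and 0.639.

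Whether an effect changed with age was tested directly. For E2F1DP, 899 transcripts had a more positive and 784 a more negative effect at 24h than at L3, and 818 and 618 did at 36h compared with 24h. For Cbt the counts were 353 and 48, then 107 and 204. Median centring moved the share of more positive calls for the later E2F1DP change from 57.0% to 39.7%, and quantile normalization to 50.9%, so the direction of that excess is not settled. The effect of Cbt on sle was 1.20 (SE 0.28, limma adjusted p = 0.011) higher at 24h than at L3, and its effect on Fatp1 was -0.99 (SE 0.24, adjusted p = 0.0219) lower at 36h than at 24h. Both of these calls ended with the slide as a term (adjusted p = 0.852 and 0.942) and with median centring (0.098 and 0.0802), and that of Fatp1 also without any of control replicates 2 and 3 and Cbt replicate 3 at 24h, or control replicates 2 and 3 and Cbt replicates 2 and 4 at 36h (0.0527 to 0.0734). Modelling the slide left 1438 and 645 transcripts for E2F1DP, and 65 and 20 for Cbt, while array weights gave 3145 and 2393 for E2F1DP and 669 for the earlier Cbt change. Without Cbt replicate 4 of 36h the last count, 311 in the full data, was 204.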

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

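The test without the 2 outlying arrays, all tests of the axis they share, the regroupings with pairs and the camera test of developmental groups were chosen after the result was seen, as were the named genes listed here. The other tests in this part were set before their own results were seen.

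The effect of E2F1DP differed between stages for many transcripts. Between L3 and 24h 1683 transcripts differed, a count reached by 4 of 100 regroupings of the arrays, the real one included (highest other 2570). With the replicate numbers of 24h kept as pairs, 70 of 560 regroupings (12.5%) reached it. Between 24h and 36h 1436 differed, a count reached by 6 of 100 (highest other 3143), and by 35 of 560 (6.25%) with pairs. For Cbt 401 transcripts differed between L3 and 24h, reached by 2 of 100 (highest other 558). Between 24h and 36h 311 differed, reached by 3 of 100 (highest other 603). Every other regrouping that did as well, with or without pairs, kept the labels of a whole stage as they were or exchanged them all. The high counts thus hold the difference between lines at that stage and are not draws of chance alone. These shares reflect how often a regrouping leaves a stage whole. For neither line can they decide whether the differences between stages arose by chance. Without Cbt replicate 4 of 36h the last count was 204.

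Among named genes, the E2F1DP effect was more positive at 24h than at L3 for NaPi-III by 3.49, sle by 1.54, SuUR by 1.46, Wdr24 by 0.88 (SE 0.26, limma adjusted p = 0.025), Uba1 by 0.78 (SE 0.24, adjusted p = 0.0276) and HDAC3 by 0.77. The calls of Wdr24 and Uba1 ended without any of several single arrays: for both control replicates 1 and 4 and E2F1DP replicate 2 of L3, control replicate 2 and E2F1DP replicate 4 of 24h, for Wdr24 also control replicate 3 of 24h, and for Uba1 also E2F1DP replicates 1 and 3 of L3 and control replicate 1 of 24h (adjusted p 0.0506 to 0.0705). At 36h compared with 24h the E2F1DP effect was more negative for Fatp1 by -2.26 and for fend by -1.43. The Cbt effect on sle was 1.20 more positive at 24h than at L3, and that on Fatp1 was -0.99 at 36h compared with 24h, with the limits given for both in the comparison of ages.

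Of the unnamed transcripts, FBtr0074485 had an E2F1DP effect that was larger by 4.79 at 24h than at L3 and by a further 1.74 (limma adjusted p = 0.0167) at 36h, and for FBtr0100257 the effect changed by -9.37 from 24h to 36h. Each of these values uses a group mean among the dimmest 25% of transcripts, so their sizes are not exact, and that of 1.74 uses such control means at both stages. For FBtr0088213 the E2F1DP effect changed by -1.57 (limma adjusted p = 0.0025) from L3 to 24h and the Cbt effect by -2.36 (adjusted p = 3.49e-05), the latter with a dim Cbt mean at 24h. The E2F1DP effect on FBtr0088213 then changed by 1.07 (adjusted p = 0.0405) from 24h to 36h, a call that ended without any of control replicates 1, 2 and 4 or E2F1DP replicates 1 and 3 of 24h, or any of control replicates 1 to 4 or E2F1DP replicates 1 and 2 of 36h (0.0508 to 0.0958), and also with the slide as a term (0.298), median centring (0.0749), quantile normalization (0.082), the intensity trend (0.0552) and without the 2 outlying arrays (0.0978).

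Single arrays far from the others of their group were looked for in 128 sets of 4 arrays, of which 9 had one, where chance gives about 1 in 20. The median log2 intensity of E2F1DP replicate 3 at 24h was 9.25, where the others lay at 9.68 to 9.72. Control replicate 1 of L3 lay at 0.0672 on the line from L3 to 36h, the others at -0.0296 to -0.0166. HDAC3 was at 13.50 in control replicate 2 of 24h (others 13.68 to 13.71), Uba1 at 14.54 in Cbt replicate 1 of 36h (others 13.86 to 13.93), fend at 9.65 in Cbt replicate 4 of 24h (others 10.12 to 10.19) and CG16974 at 13.09 in E2F1DP replicate 2 of 36h (others 13.49 to 13.53). FBtr0074485 was at 11.52 in Cbt replicate 1 of L3 (others 11.19 to 11.22). In control replicate 4 of 24h, FBtr0077115 was at 9.62 (others 7.62 to 7.95) and FBtr0088213 at 11.58 (others 11.22 to 11.26).

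In the first pattern weighed, E2F1DP wings at 24h and 36h lay nearer to larval control wings than their own controls did. The difference in position at 24h kept 99.7% of its size with one of median centring and quantile normalization and 101% with the other. A shift of a whole array hardly moves its position, since about as many transcripts rose as fell along the line (3320 and 3732). Median centring thus cannot decide on array scaling, and quantile normalization speaks only against differences between arrays in the distribution of values. The tables argue against the outlying arrays, since the difference kept 98.1% without them. A developmental delay of the E2F1DP wings may account for much of the pattern, and this stays a hypothesis. As the whole cause it was predicted to leave under 5% of the transcripts that are stable in control development changed. Of 4891, 9.85% were changed at 24h and 7.05% at 36h, short of the 10% set as evidence against a delay. These bounds cannot decide, since stability was read at the sampled stages only. Transcripts that change only between those stages could differ in a delayed wing. The stable set was also chosen on control arrays, some of which these contrasts use. A direct rise of early-stage transcripts alone would not lower those that rise in control development, of which 1433 of 3320 were lower and 106 higher at 24h (camera adjusted p = 0.0115 with an estimated correlation). Effects of E2F1 and DP on both groups of transcripts, direct or not, were not tested and stay open beside a delay.

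In the second pattern, control replicate 3 and E2F1DP replicate 3 at 24h stood apart from their groups in the same way. Their deviations had r = 0.73 across transcripts, their array medians were the lowest of all, at 9.28 and 9.25, and they headed an axis that held 24.3% of the variance within groups, with scores of 75.8 and 77.1 where the next array had 34.8. The tables argue against the slide, since the highest score among the 3 arrays of other groups on their slides was 2.50, and against a shared handling of all samples numbered 3, whose median score in the other 7 groups was 1.58 (highest 25.8). They argue against a swap of the labels between the groups, since control replicate 3 lay at 0.674 in development, above the midpoint of 0.518 between the groups. A common day of collection or RNA quality stays open and was not tested, and the design gives no biological explanation to test.

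In the third pattern, both lines changed the same transcripts in the same direction. The tables argue against noise of the shared control arrays, since with the controls split the lowest ratio of shared transcripts to that of independent lists was 3.37 at 24h and 5.15 at 36h. A lag of both lines in development may add to the overlap. Among the 4891 transcripts stable in control development, the 6 splits shared only 10 to 17 at 24h and 3 to 9 at 36h. Across all these stable transcripts the changes of both lines had a mean r of -0.0259 at 24h and -0.0346 at 36h with the controls split. The ratio among them averaged 3.65 at 24h and 6.15 at 36h over the 6 splits, past the bound of 3 set against a lag alone. That bound was also set for the lowest split, which at 2.01 and 2.67 stayed under it and above the 1.5 set for a lag. A lag and a shared response to transgene expression thus cannot be told apart. The limit of the stable set named in the first pattern applies here too.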

How the results depend on the processing

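Leaving out the 2 outlying arrays together and the tests over pairs of positions and of developmental groups were chosen after the result was seen. The other alternatives were set beforehand.

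No named value reversed: of 2484 recomputed, 2233 kept their direction and call and 251 lost the call. Only values called in the main model were recomputed, for the named genes and the unnamed transcripts given as examples. The series table, unmerged features, the filter, the intensity trend, the thresholds and modelling only the compared groups leave the estimate as it is. Those alternatives could not reverse a value. Each of the 16 counts of changed transcripts stayed within 1.5 times its value with the slide as a random term, with the replicate number or the array position as a term, with median centring, quantile normalization, the filter on dim transcripts and the intensity trend, and the series table and unmerged features give identical values. With the replicate number as a term E2F1DP against control at 24h, the contrast whose numbers passed the check for pairing, gave 4294 against 4171. There it ended the call of FBtr0077115 (-1.02, limma adjusted p = 0.0563) and, in an exact test over 4 pairs, that of the position (-0.358, exact p = 0.125, the smallest possible). It changed no other call of that contrast named in the text, and camera kept both developmental groups (adjusted p = 0.000899 and 0.0111 with an estimated correlation). The cause of a move was not tested unless one is given.

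With the slide as a fixed term, which leaves 18 residual degrees of freedom in place of 26 and wider errors, the counts were 79 for E2F1DP at L3, 51, 392 and 622 for Cbt at L3, 24h and 36h, 98 for Cbt against E2F1DP at L3 and 1999 for control 36h against 24h. The changes of effect gave 645 for E2F1DP from 24h to 36h, and 65 and 20 for Cbt, and the overlaps of both lines were 4, 227 and 362. All transcripts called both ways had the same sign. The correlation between arrays of a slide, estimated over all transcripts for the random term, was -0.0109. The model with the random term was thus close to the main one and adds little as a check. Correlations with control development became -0.0975 for E2F1DP and -0.234 for Cbt at L3, and -0.0684 for Cbt at 36h.

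Array weights raised the counts to 801 for E2F1DP at L3, 458 and 1823 for Cbt at L3 and 36h, 2089 for Cbt against E2F1DP at L3, 3145 and 2393 for the changes of the E2F1DP effect and 669 for that of Cbt from L3 to 24h. The overlaps were 83 at L3 and 1040 at 36h, and the correlations at L3 -0.0615 for E2F1DP and -0.0989 for Cbt.

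A log2 change of at least 1, which by construction keeps part of the calls, left 88, 2000 and 1821 for E2F1DP at L3, 24h and 36h, 79, 755 and 637 for Cbt, and 204, 1683 and 1696 for Cbt against E2F1DP. Control kept 3108 for 24h against L3, 1581 for 36h against 24h and 4213 for 36h against L3, and the overlaps were 402 at 24h and 333 at 36h. An adjusted p under 0.01, which also keeps part of the calls, left 55 for E2F1DP at L3, 71, 713 and 678 for Cbt, 177 for Cbt against E2F1DP at L3 and 2219 for control 36h against 24h. The changes of effect kept 1035 and 876 for E2F1DP and 228 and 159 for Cbt, and the overlaps 5, 401 and 388.

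With only the compared groups in the model, and so fewer arrays, E2F1DP at 24h gave 2186, Cbt 443 at 24h and 698 at 36h, Cbt against E2F1DP 1143 at L3 and 1968 at 24h, and the change of the Cbt effect from 24h to 36h 113. The overlaps were 9, 242 and 376.

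With 2 control arrays per line, and so fewer controls, the 6 ordered splits gave overlaps at L3 of 3, 3, 3, 5, 3 and 4, at 36h of 376, 337, 425, 314, 387 and 343, and at 24h, in the 3 splits that moved most, of 328, 399 and 363. Without the 2 outlying arrays, E2F1DP at L3 gave 206, Cbt against E2F1DP at L3 489, and the overlap at L3 23.

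The correlation of the E2F1DP effect at L3 with control development, r = -0.04, was -0.0218 with the replicate number and -0.184 with the array position as a term, -0.0201 with quantile normalization, -0.0907 with the filter on dim transcripts and -0.113 without the 2 outlying arrays. Over only the transcripts changed between control stages, a smaller set chosen for its control change, the correlations were -0.169, -0.660 and -0.405 for E2F1DP at L3, 24h and 36h and -0.234 and -0.389 for Cbt at L3 and 24h.

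Leaving out each array in turn gave 51 to 126 for E2F1DP at L3, with 88 without control replicate 4 and 51, 64 and 53 without E2F1DP replicates 1, 2 and 3. Cbt against E2F1DP at L3 ranged from 173 to 254, with 173, 212 and 182 without the same replicates. The overlap at L3 ranged from 7 to 16, with 7, 9 and 7 without E2F1DP replicates 1, 2 and 3, and 9 and 8 without Cbt replicates 2 and 3. The change of the Cbt effect from 24h to 36h ranged from 204 to 370, lowest without Cbt replicate 4 of 36h. The correlations at L3 ranged from -0.113 to 0.0505 for E2F1DP and from -0.214 to -0.0504 for Cbt, each lowest without control replicate 4 and highest without control replicate 1. The position of Cbt at 36h against control ranged from -0.0771 to -0.0426, and passed only without control replicate 1 of 24h (-0.0684, exact p = 0.0286). No other count moved by more than 1.5 times.

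Signal over background was not analysed here, and the number of arrays limits what can be seen: on simulated data 56.2% of log2 changes of 1 were found at 24h and 50.7% at L3.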

Other observations

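The direct comparisons with control at 24h, the regroupings with replicate numbers as blocks and the look at transcripts changed in both lines were chosen after the result was seen. The other splits of the samples were set before their results were seen.

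Compared with control at 24h, E2F1DP wings at 36h differed in 2900 transcripts (1430 higher, 1470 lower, limma), and Cbt wings at 36h in 3856 (1844 higher, 2012 lower). Control wings at 36h differed from control at 24h in 3587. One transcript was higher in both lines at all 3 stages and 4 were lower, and their cause was not tested.

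All arrays of each comparison were regrouped in every other way, 35 splits with the real one. For each line against control and for Cbt against E2F1DP, 1 split of 35, the real one, gave as many transcripts. That is the smallest share that 35 splits can give, and it was not adjusted for the number of comparisons. It argues against chance at each stage if the samples are independent, as the labels say. For E2F1DP the real counts were 133, 4171 and 3656 at L3, 24h and 36h, and the highest other splits gave 32, 3024 and 28. For Cbt they were 119, 1209 and 1129 against 6, 394 and 189, and for Cbt against E2F1DP 320, 3615 and 3634 against 41, 1392 and 246. In control, 24h against L3 gave 5654 against 1041, 36h against 24h gave 3587 against 274, and 36h against L3 gave 7052 against 526. The split with 3024 transcripts set control replicates 1, 2 and 3 with E2F1DP replicate 3 against the rest. The replicate numbers of E2F1DP and control at 24h passed the check for pairing. If they do pair the samples, the real split has to be set beside the 8 splits that part all 4 pairs, which are too few for a share under 0.05. The real one of these gave 4171 and the highest other 22, while the splits that keep some pairs together gave up to 3024.

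The overlap of both lines was tested on 100 regroupings of the arrays of a stage. The real overlaps of 14 at L3 and 651 at 36h were reached by 1 of 100, the real one (highest others 10 and 37), and that of 698 at 24h by 2 of 100 (highest other 1027). With the replicate numbers of 24h as blocks, the overlap at 24h was reached by 15 of 648 regroupings (2.31%, highest other 2821). Regrouping also removes the effect of each line on its own, so these shares speak only against groups of arrays that do not differ. They cannot tell whether 2 real effects share more transcripts than independent lists would, which at 36h already share 135, above the 37 of the highest regrouping. At L3 the overlap was of few transcripts: it was 7 without E2F1DP replicate 1 or 3, below the 10 of the highest regrouping, though regroupings were not drawn for fewer arrays. It was 4 with the slide as a term and 3 to 5 with the controls split, and the covariance of the changes at L3 did not exceed that of simulated unchanged groups (0.0419 against 0.0464). The regrouping with 1027 at 24h made the control group from control replicate 3 and E2F1DP replicates 1, 2 and 3.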
